A study of Homo sapiens with 6 samples.

How the data were processed

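RNA of MCF7 cells was measured in 6 libraries, 3 labelled as control without overexpression and 3 labelled as UBP1 overexpression, all at day 2. Per the labels' protocols, the cells were grown in DMEM with serum and total RNA was taken with Trizol. The series text describes 3′ mRNA sequencing with QuantSeq, whereas the labels' protocol names a kit for small RNA libraries, and this conflict could not be settled from the files.

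Each deposited file held raw read counts per gene symbol, not normalized. Per the submitters' processing notes, Bowtie2, bedtools and edgeR were used, with no versions, roles or order given. The genome build and annotation were not given in the sources used here, and whether reads were counted by strand is not stated, so overlapping and antisense genes cannot be separated. The tables listed 25737 rows and 24462 symbols. A group of 286 symbols filled several rows (1.16% to 1.37% of the counts), and each row was kept as deposited, with the row of the highest total bearing the plain symbol. There were 0 rows without a gene name. Totals per library ran from 7805209 to 9596479 counts, and 15827 to 16543 rows had at least 1 count.

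Samples were grouped by their labels. Counts were analysed in R 4.3.3 with edgeR 4.0.16: rows were filtered with filterByExpr, scaled with TMM (factors 0.98 to 1.03), and tested with the robust quasi-likelihood test, and p-values were adjusted with Benjamini-Hochberg over the 13337 tested rows at a threshold of 0.05. The biological coefficient of variation was 22.2%. Standard errors were derived from the log2 fold and the F statistic. CPM values used the TMM-scaled library sizes. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry, for the 29 of 34 lists that had at least 5 tested members. The 34 lists, the tests, the other settings and the rule for named genes were set before the data were examined. The rule named UBP1 and its family, up to 12 rises and 12 falls past the threshold with a mean of at least 5 CPM and groups that did not overlap, up to 4 members per list by p, and 8 well-known luminal, junction and proliferation genes; genes outside it are said to have been chosen afterwards.

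Each pair of libraries differed by more than the noise of counting reads (chi-square per degree of freedom of 6.65 or more), so no library was treated as a copy of another. This cannot tell separate cultures from repeat preparations of the same culture. The mean Pearson correlation of log2 CPM was 0.969 within control, 0.953 within UBP1 samples and 0.95 between groups. Alternatives were other scalings, DESeq2 1.42.0, limma-voom, other filters, a fold minimum of 1.5, the replicate number as a block and leaving out each library. Summing rows of one symbol, an offset for GC content, and the GC offset together with a left-out library or the block were tried as well, chosen after seeing the data. GC content was taken from the last 500 nt of the longest transcript in GENCODE release 29, matched by symbol for 12544 tested rows (94.0%), and the offset was a lowess curve (span 0.5) per library.

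The edgeR steps were tested on simulated counts for UBP1 overexpression against control, with 200 changed genes. Of the changes of 1.5-fold, 2-fold and 4-fold, 10.4%, 68.7% and 98.5% were recovered, and 12 of 130 calls were false among 13104 genes. Changes of 1.5-fold are thus mostly missed at this depth and spread, and folds between 1.5 and 2 were not simulated. With a GC trend like that of the libraries added to the simulated counts, 30 of 154 calls were false without the GC offset, as in the main fit, and 22.4%, 68.7% and 95.5% of the changes were recovered; with the offset 13 of 140 calls were false.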

Results

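The transcriptome of MCF7, an established line of oestrogen receptor-positive, luminal breast cancer cells, was compared between 3 control samples labelled as receiving no overexpression and 3 samples that overexpressed UBP1, all taken at day 2. UBP1 (upstream binding protein 1) is a transcription factor of the CP2 and grainyhead family, and the series was set up to examine it in breast cancer progression. The deposited libraries held 8482599, 9055593 and 9596479 counts in the control samples and 9279358, 7805209 and 9270379 in the UBP1 samples. After the low-count filter, 13337 rows were tested. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The genome build behind the counts was not given in the sources used here, and genes are therefore named by symbol only, without coordinates.

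UBP1 itself was measured first. Its counts were 545, 677 and 696 in the control libraries and 1039, 756 and 959 in the UBP1 libraries, which corresponded to 69.6 ± 6.45 CPM (counts-per-million, scaled by TMM; mean ± SD, n = 3) and 106 ± 7.87 CPM (n = 3). Every UBP1 library lay above every control library, and the fold was 1.52 (log2 0.60, SE 0.14). In the fit across all genes this difference missed the threshold (edgeR quasi-likelihood test, adjusted p = 0.0862), and the two-sided exact permutation test gave p = 0.1, the smallest value that 3 libraries against 3 allow. It passed with DESeq2 (adjusted p = 0.00733) and with UBP1 overexpression replicate 1 left out (adjusted p = 0.00729 with edgeR), and the adjusted p ranged from 0.000696 to 0.501 over all alternatives. Counts near the 3′ end of a transcript need not include a construct that lacks the native 3′ untranslated region, so this value need not measure the amount of UBP1 introduced; the labels do not describe the construct. Among the relatives of UBP1, GRHL1 stood at 53.5 ± 9.86 CPM in control and 34.98 ± 19.7 CPM in UBP1 samples (log2 -0.61, adjusted p = 0.478) and GRHL2 at 45.5 ± 9.01 and 39.9 ± 3.42 CPM (adjusted p = 0.61). The UBP1 libraries 1, 2 and 3 held 57.6, 25.9 and 21.4 CPM of GRHL1, and without UBP1 overexpression replicate 1 it was lower in the remaining UBP1 libraries (log2 -1.18, adjusted p = 0.000138). GRHL3 and TFCP2 had too few counts to be tested, and TFCP2L1 had 0 counts in all 6 libraries.

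Genes of the interferon response were higher in UBP1-overexpressing cells. IFI27, an interferon-induced mitochondrial protein, rose from 438 ± 24.3 to 898 ± 18.4 CPM (n = 3 each; 2.05-fold, log2 1.03, SE 0.10, adjusted p = 0.000218). The antiviral membrane proteins IFITM1 and IFITM3 rose 1.84-fold (adjusted p = 0.000985) and 1.72-fold (adjusted p = 0.00908). IFIT3 rose 1.87-fold and IFI6 1.59-fold (adjusted p = 0.0259 for both). PSMB9, a subunit of the immunoproteasome, and OAS2, an oligoadenylate synthetase, rose 2.20-fold and 1.61-fold (adjusted p = 0.0436 for both). Of the 50 tested members of the interferon list, 43 had a positive fold, 7 passed as higher and 0 as lower over all genes, and 21 were higher and 0 lower when adjusted over the list alone. The list median was a log2 fold of 0.37, and the list was higher than the other genes (camera with a preset correlation, adjusted p = 3.44e-15; adjusted p = 0.0204 with an estimated correlation). Its median difference to the control mean was 0.43, 0.37 and 0.41 on the log2 scale in UBP1 libraries 1, 2 and 3, against values between -0.04 and -0.01 in the control libraries. ISG15, a ubiquitin-like interferon-induced protein that was chosen after its values were seen, had a fold of 1.47 without passing over all genes (adjusted p = 0.0851). IRF9, a subunit of the interferon-activated transcription factor ISGF3 and likewise chosen afterwards, had a fold of 0.765 (adjusted p = 0.277). IFITM1 and IFITM3 have near-identical relatives, and PSMB9 overlaps PSMB8 on the opposite strand, so reads of these genes may be shared.

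**Figure D1:**
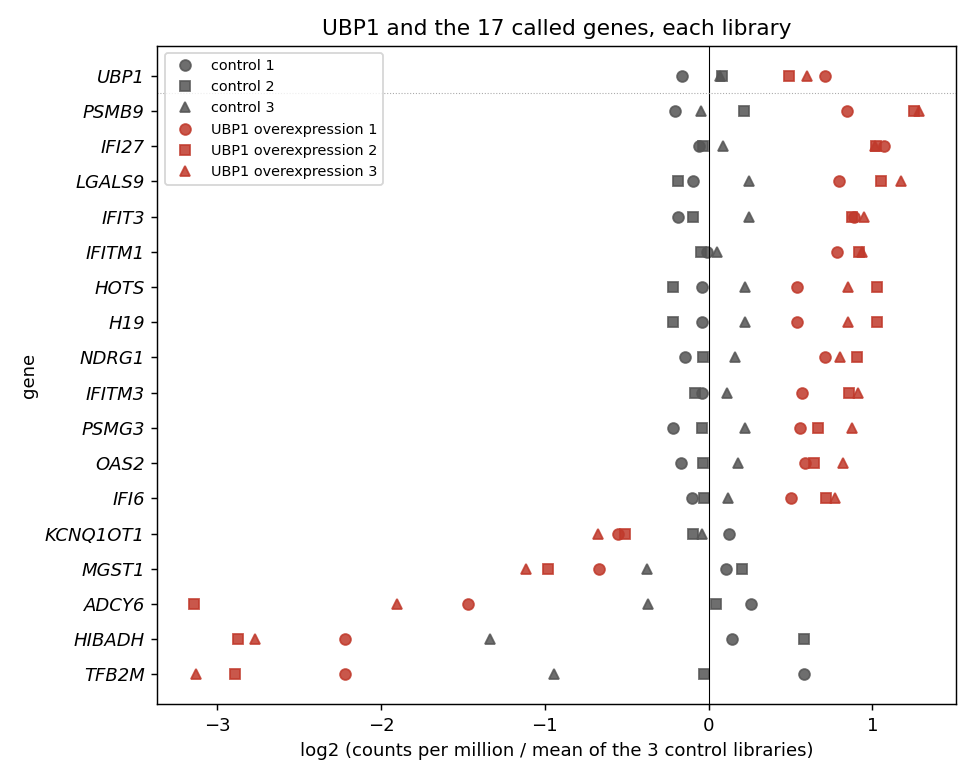
UBP1 and the 17 genes past the threshold (vertical axis) are drawn with the log2 ratio of each library's CPM to the mean of the 3 control libraries (horizontal axis). Grey points are control libraries, red points are UBP1 overexpression libraries, and the marker shape gives the replicate number. In each gene the 3 UBP1 libraries lie on one side of the 3 control libraries.

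Across all genes, 17 passed the threshold of 0.05, 12 of them higher and 5 lower in UBP1 samples. Besides the 7 interferon genes, the higher genes were LGALS9 (galectin 9; 2.02-fold), NDRG1 (a hypoxia- and stress-induced gene; 1.75-fold, adjusted p = 0.00809), PSMG3 (a proteasome assembly chaperone; 1.63-fold), and the imprinted non-coding RNA H19 with HOTS, both 1.77-fold; each had an adjusted p of 0.0436 unless given otherwise. H19 and HOTS had nearly the same counts in each library (for example 4427 and 4423 in control 1), so they stand for a single locus, although both rows are among the 17. The lower genes were TFB2M, a mitochondrial transcription factor (8.67 ± 4.25 to 1.34 ± 0.46 CPM), HIBADH, an enzyme of valine breakdown (14.2 ± 7.95 to 2.37 ± 0.61 CPM), the adenylyl cyclase ADCY6 (20.6 ± 4.39 to 5.10 ± 2.58 CPM), the microsomal glutathione transferase MGST1 (0.532-fold), and KCNQ1OT1, an imprinted non-coding RNA (0.67-fold, adjusted p = 0.0482), with an adjusted p of 0.0436 in the other 4. TFB2M and HIBADH rested on 9 to 28 counts per UBP1 library. ADCY6, KCNQ1OT1, LGALS9 and PSMG3 overlap other annotated genes, and whether reads were counted by strand is not stated. Over all tested genes, 2260 had an unadjusted p under 0.05, 1089 higher and 1171 lower, and in 2802 genes (21.0%, against 10% by chance) the groups did not overlap. The nuclear non-coding RNA MALAT1, chosen after its values were seen, took 3.25%, 2.67% and 2.63% of the counts in control and 2.17%, 2.28% and 1.90% in UBP1 libraries without passing (log2 -0.38, adjusted p = 0.127; 0.00934 without UBP1 overexpression replicate 1).

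The number of calls depended on single libraries. It was 2129 without UBP1 overexpression replicate 1 (820 higher and 1309 lower), 182 without control replicate 3, and 2 without any of control replicate 1, control replicate 2, UBP1 overexpression replicate 2 or UBP1 overexpression replicate 3, while DESeq2 called 360 genes. Of 47 genes besides UBP1 that were followed through the alternatives and missed the threshold with all libraries, 37 passed without UBP1 overexpression replicate 1, among them ATF4 (adjusted p = 0.000131) and MYC (adjusted p = 0.00391). Many of these genes were picked for a low p or after their values were seen, so that share is not typical. Over all genes, 2129 of 13733 tested passed in that fit. IFI27 and IFITM1 were called in all 17 alternative fits, and all 17 genes kept their direction in them. The groups did not overlap in any of these genes, so leaving out a library could hardly have reversed a direction.

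Genes of hypoxia and glycolysis were the next list to be higher. NDRG1 was the only member to pass over all genes. ANGPTL4, a hypoxia-induced inhibitor of lipoprotein lipase, had a fold of 1.62 (adjusted p = 0.0508), and the glycolytic enzymes TPI1 and ENO1 had folds of 1.38 and 1.40 (adjusted p = 0.0815 and 0.0862). Of 35 tested members, 26 had a positive fold, 1 was called higher and 0 lower over all genes, and 14 were higher and 0 lower adjusted over the list alone, with a median log2 fold of 0.33 (camera adjusted p = 3.01e-06). With an estimated correlation the list did not pass (camera adjusted p = 0.0559). That estimate was -0.018, below the preset of 0.01, so a stronger correlation between its genes does not account for the loss. With the offset for GC content, chosen after seeing the data, the list passed narrowly with an estimated correlation (camera adjusted p = 0.0492).

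The list of the integrated stress response, the programme downstream of the transcription factor ATF4, was also higher by camera (adjusted p = 0.00013), and this was lost with an estimated correlation (adjusted p = 0.219). Of its 30 tested members, 22 had a positive fold and 0 passed over all genes, while 11 were higher and 1 lower adjusted over the list alone, with a median log2 fold of 0.28 (0.16 with an offset for GC content, chosen after seeing the data, where camera still passed with adjusted p = 0.00271). ATF4 had 467 ± 41.4 CPM in control and 700 ± 81.3 CPM in UBP1 samples (1.5-fold, adjusted p = 0.0615). The tryptophanyl-tRNA synthetase WARS (1.41-fold), the secreted glycoprotein STC2 (1.37-fold) and the glutathione-degrading enzyme CHAC1 (1.95-fold) had adjusted p between 0.0862 and 0.0922. CEBPG, a partner of ATF4 that was chosen after its values were seen, was the member that fell (0.58-fold, adjusted p = 0.0134 over the list alone). The list call was also lost with a GC correction without UBP1 overexpression replicate 1 (adjusted p = 0.108; 3.65e-05 to 0.219 over the alternatives).

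The list of NF-kB targets and cytokines was higher by camera (adjusted p = 0.0171), but not with an estimated correlation, which was -0.055 (adjusted p = 0.219). Of 18 tested members 14 had a positive fold, 0 passed over all genes and 2 were higher and 0 lower adjusted over the list alone, namely the NF-kB inhibitor NFKBIE (1.93-fold) and the chemokine CCL5 (1.93-fold, from 8.83 ± 2.30 to 17.1 ± 2.23 CPM). The call was lost without control replicate 3 (adjusted p = 0.0599), without UBP1 overexpression replicate 1 (adjusted p = 0.179), without a low-count filter (adjusted p = 0.0514) and with the offset for GC content (adjusted p = 0.0527), where the median log2 fold was 0.21 against 0.23, and its camera adjusted p ranged from 0.0146 to 0.315 over the alternatives (fry, which does not compare the list with other genes, gave 0.000507).

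**Figure D2:**
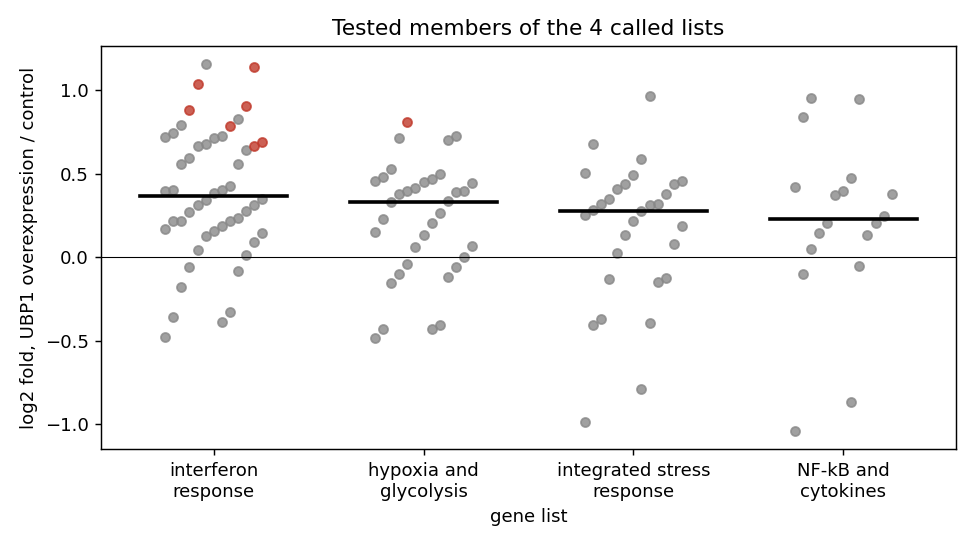
Each point is a tested gene of the 4 lists that passed the camera test (horizontal axis), at its log2 fold of UBP1 overexpression over control (vertical axis, 3 libraries per group). Red points passed the threshold over all genes and black bars are list medians, which were 0.37, 0.33, 0.28 and 0.23 from left to right.

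The remaining 25 tested lists did not pass camera, with adjusted p from 0.131 to 0.963, and none of their members passed over all genes. They included oestrogen receptor targets (40 tested, adjusted p = 0.865), luminal identity genes (19 tested, 0.493), basal and myoepithelial markers (13 tested, 0.505), epithelial junctions (25 tested, 0.963), mesenchymal genes (12 tested, 0.963), S phase and DNA replication (46 tested, 0.397), G2 and mitosis (51 tested, 0.629) and p53 targets (30 tested, 0.947). Camera tests for a shift in 1 direction, so these values do not show that single genes were unchanged. Adjusted over the list alone, 5 oestrogen receptor targets were higher and 2 lower. The counts were 1 and 1 in luminal identity, 2 and 1 in junctions, 0 and 1 in S phase, and 4 and 1 in p53 targets. The lower luminal gene was AGR3 (7.26 ± 2.64 to 1.04 ± 1.19 CPM, 0.147-fold, adjusted p = 0.0922 over all genes). ESR1, the oestrogen receptor, had 119 ± 14.9 CPM in control and 124 ± 22.7 CPM in UBP1 samples (adjusted p = 0.882), and the luminal factor GATA3 had 2337 ± 80.0 and 2098 ± 125 CPM (adjusted p = 0.427). The pioneer factor FOXA1 stood at 121 ± 43.7 and 67.2 ± 9.50 CPM (adjusted p = 0.197). E-cadherin (CDH1) had 529, 566 and 498 CPM in the control libraries and 524, 239 and 266 CPM in UBP1 libraries 1, 2 and 3 (log2 -0.63, adjusted p = 0.408); without UBP1 overexpression replicate 1 it passed as lower (log2 -1.07, adjusted p = 4.47e-07). Vimentin (VIM) had 4.13 ± 1.20 and 2.03 ± 0.62 CPM (adjusted p = 0.334). For proliferation, MKI67 had 78.9 ± 7.26 and 85.2 ± 15.3 CPM (adjusted p = 0.76) and CCND1 516 ± 44.6 and 628 ± 35.4 CPM (adjusted p = 0.197). MYC was low in both groups, at 8.28 ± 2.18 and 2.66 ± 1.497 CPM (adjusted p = 0.127). Among the lowest p-values of these lists were the oestrogen-regulated TFF3 (1.38-fold, adjusted p = 0.0851), the tight junction gene CLDN7 (0.684-fold, 0.0862), the cell cycle gene CDCA7 (0.246-fold, 0.0922), the p53 targets BBC3 (1.48-fold, 0.0817) and CDKN1A (1.32-fold, 0.104), and the chaperone HSPA5 (1.40-fold, 0.0815). In the oestrogen receptor list and the mesenchymal list the median log2 fold (-0.08 and -0.02) and the camera direction (higher) differed in sign. The lists of immediate early genes, antioxidant genes and epithelial junctions had medians of 0.02, 0.04 and 0.01 and a camera direction of lower.

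Few markers of other cells reached the filter. Of 20 haematopoietic markers 1 reached the filter, and of 18 fibroblast and endothelial markers 7 did, with a camera adjusted p of 0.629. Of 15 genes of HEK293 cells and the neural lineage 3 did, too few for a list test. All 3 had a positive fold and 2 were higher adjusted over the list alone (adjusted p = 0.0473 for both): SOX2, a stem cell transcription factor, at 46.0 ± 4.32 CPM in control and 60.4 ± 8.999 CPM in UBP1 samples (adjusted p = 0.229 over all genes), and TUBB3, a neuronal tubulin, at 125 ± 6.30 and 151 ± 8.64 CPM (0.249). With the offset for GC content, chosen after seeing the data, the log2 fold of TUBB3 went from 0.28 to 0.12 and that of SOX2 from 0.39 to 0.61. Neither passed over all genes with it (edgeR adjusted p = 0.684 and 0.127).

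The libraries also differed along an axis that did not follow the groups. The first principal component (42.9% of the variance) placed UBP1 libraries 2 and 3 at 45.7 and 46.6, whereas UBP1 library 1 (-13.3) lay with the control libraries (-31.4, -37.5 and -10.2). The second component (17.7%) set UBP1 library 1 apart at -38.5, against 17.35, 8.29 and 4.10 in control and 26.1 and -17.4 in UBP1 libraries 2 and 3. Pearson correlations of UBP1 library 1 were 0.9621, 0.9635 and 0.9646 with the control libraries, and 0.9462 and 0.9494 with UBP1 libraries 2 and 3. Counts also moved with the GC content of the transcript's last 500 nt. Per 10 points of GC, the log2 counts relative to the mean of the libraries changed by -0.07, -0.09 and -0.02 in control libraries 1, 2 and 3 and by -0.02, 0.09 and 0.12 in UBP1 libraries 1, 2 and 3 (two-sided exact permutation test, p = 0.2). The median GC content was 54.8% in the genes called higher, 35.2% in those called lower and 42.4% in all tested genes. With an offset for this trend, chosen after seeing the data, 26 genes were called, 15 of them among the 17. PSMG3 (1.48-fold, adjusted p = 0.0636, against 1.63-fold without the offset) and KCNQ1OT1 (0.70-fold, adjusted p = 0.0647, against 0.67-fold) no longer passed. The interferon list had a median log2 fold of 0.39 (camera adjusted p = 2.68e-16).

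**Figure D3:**
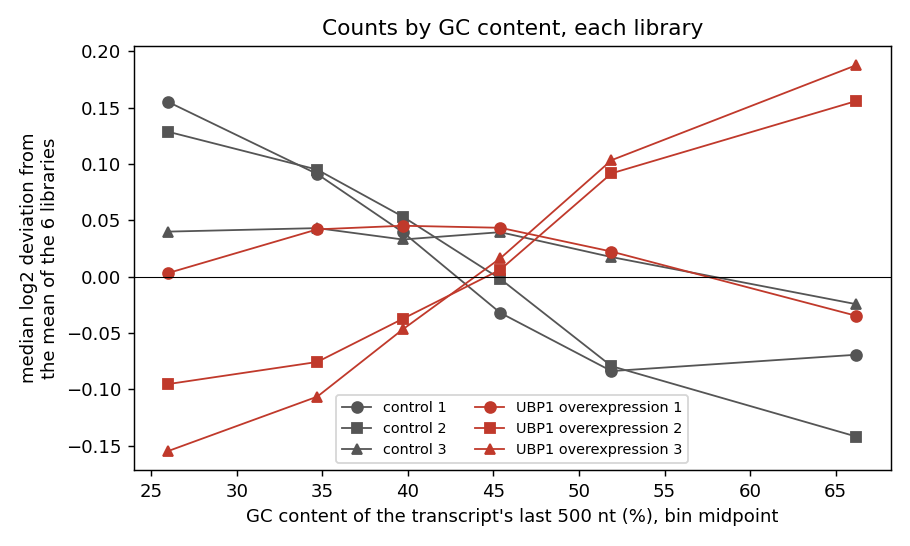
Tested genes were split into 6 bins by the GC content of the last 500 nt of their longest transcript (horizontal axis, bin midpoint in percent), and each library's median log2 deviation from the mean of the 6 libraries is drawn (vertical axis). Grey lines are control libraries and red lines UBP1 overexpression libraries. In the bin with the highest GC content UBP1 libraries 2 and 3 lie at 0.16 and 0.19, and UBP1 library 1 (-0.03) lies beside control library 3 (-0.02).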

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

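Of the results with a test or count, the number of called genes moved most. Against 17 calls (12 higher, 5 lower; 70.6% higher), total count scaling gave 6 (all higher), DESeq2 360 (38.3% higher), no low-count filter 666 (36.2% higher), and the fits that leave out a library 2 to 2129. The cause was not tested for DESeq2 and the filter. Other scaling with DESeq2's size factors (19), limma-voom (17), a minimum of 5 CPM (21), a fold minimum (16) and summed rows (17) stayed close. The GC offset, chosen after seeing the data like all settings with it and the summed rows, gave 26 calls, and 1764 without UBP1 overexpression replicate 1. UBP1 had a log2 fold of 0.53 to 0.66 when a library was left out, and passed with DESeq2 (0.61), without a low-count filter (0.60), without UBP1 overexpression replicate 1 (0.55), with the GC offset (0.75) and with the GC offset without that library (0.74). Of the lists, 4 passed in the main setting, 3 to 5 with a library left out, 1 with an estimated correlation, 7 with fry (which adds ribosome biogenesis as higher, and G2 and mitosis and the basal markers as lower), and 2 with the GC offset without UBP1 overexpression replicate 1. Genes that never passed changed sign: GRHL2 with the GC offset (log2 0.0086), with it without UBP1 overexpression replicate 1 (0.0571) and with the replicate block and GC offset (0.0183). With a library left out, ESR1 ranged from -0.1025 to 0.1608, negative without control replicate 2 (-0.0022) or UBP1 overexpression replicate 2, and MKI67 from -0.0273, without UBP1 overexpression replicate 2, to 0.2344. Over the 64 single genes besides UBP1 and the 4 called lists that were followed through the alternatives, and leaving out the changes of sign just given, 904 values stayed on their side of the threshold, 157 passed it newly and 86 lost it, all in the same direction.

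With the replicate number as a block, 86 genes (31.4% higher) and 4 lists were called, and with the block and the GC offset 95 genes (32.6% higher) and 3 lists, where UBP1 passed (log2 0.75). The deviations of libraries with the same number correlated at 0.02, -0.12 and 0.11, and these correlations gave no sign of pairing by number. In the simulated counts, which had no pairing, the block gave 135 calls against 130 without it. The rise from 17 to 86 was larger, and its cause was not tested. The labels do not say whether a number marks a shared culture or day, so pairing is not excluded.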

Other observations

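Tests chosen after the result was seen are those of the antigen processing and imprinted lists, the construct, the mislabelled library, the shared response, the response along GC content, and the splits for the gene count; the GC offset was also chosen after seeing the data, before its effect on these results was known.

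Genes of MHC class I antigen processing, a list written after the gene table was seen, were mostly higher in UBP1 samples. Because the list was written with these values in view, its p values do not test whether such genes rise as a group. Of 20 tested members 15 had a positive fold, with a median log2 fold of 0.26 (camera p = 4.07e-05 with the preset correlation and p = 0.011 with an estimated correlation). Without the 3 members that the interferon list also holds, the median was 0.24 and the p values were 0.00112 and 0.0247. With the GC offset the camera p values were 0.000323 (preset correlation) and 0.0249 (estimated correlation), or 0.00545 and 0.0402 without these members. The medians were smaller with it, at 0.20, and at 0.15 without these members, so part of the rise may follow GC content. The peptide-loading factor TAPBP had a fold of 1.5 (edgeR adjusted p = 0.0752), HLA-B 1.46 (0.0799) and the proteasome activator PSME2 1.41 (0.102), while HLA-F had 0.355 (0.287). HLA genes have near-identical relatives that may share reads. Of the interferon genes themselves, chosen after their values were seen, IFNB1 had 15 counts over all 6 libraries, and IFNL1 had 4.34, 8.50 and 5.87 CPM in control and 10.5, 12.7 and 13.3 CPM in UBP1 libraries (log2 fold 0.96, adjusted p = 0.16; 1.06 and 0.0305 without UBP1 overexpression replicate 1).

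Imprinted genes had an unadjusted p under 0.05 more often than other genes: 9 of 27 (33.3%) against 16.9% (Fisher's exact test, p = 0.0356). The list was written because H19 and KCNQ1OT1 had been called, and without the called genes the difference did not pass (Fisher's exact test, p = 0.174), so whether imprinted genes as a class change more often stays undecided. Of the 9 genes, 3 were higher and 6 lower, among them PHLDA2 (1.40-fold, edgeR adjusted p = 0.0897) and MEST (0.455-fold, 0.0615).

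The rise of the interferon list was weighed against technical explanations. With the GC offset its median log2 fold was 106% of the uncorrected value. The lowest median with a library left out was 91.4% of that with all, and the lower of both other scalings gave 88.1%. GC content, a single library or library scaling therefore do not account for the rise of the list as a whole. Its 7 called members still passed with the offset, but several had smaller log2 folds. IFITM3 went from 0.79 to 0.62, IFITM1 from 0.88 to 0.74, IFI27 from 1.03 to 0.90 and IFI6 from 0.67 to 0.57. PSMB9 went from 1.14 to 1.09, OAS2 stayed at 0.69, and IFIT3 went up from 0.90 to 0.99. An effect of introducing a construct and an effect of UBP1 itself cannot be told apart, since 0 of the libraries are labelled as carrying an empty construct. A response to UBP1 stays open as a hypothesis.

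Many genes moved with GC content between libraries. GC bias may account for part of the calls made without UBP1 overexpression replicate 1. With the GC offset 82.9% of their number (1764 against 2129) was still reached, so the trend that the offset removes does not account for the whole number. Only numbers were compared, not whether the same genes stayed called, and bias that the offset misses was not tested. Whether the trend is a response to UBP1 cannot be told apart from other differences between the libraries: the slopes of the groups overlapped (gap -0.0029, against a range of 0.136 within the UBP1 libraries), and the overlap rests on UBP1 overexpression replicate 1 (-0.0207) and control replicate 3 (-0.0178).

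UBP1 overexpression replicate 1 lay close to the control libraries in many genes. Over the 2129 genes called without it, its median position was 0.249 of the way from the control mean (0) to the mean of the other UBP1 libraries (1), with 0.402 in the genes called higher and 0.175 in those called lower. A bound of 0.25 over all called genes, set after the medians of both sets were known, was met only barely; it was then replaced by the condition that the higher and the lower set both lie at or below it, which was not met, so these values do not decide whether the response is shared by all UBP1 libraries. That it is a mislabelled control is argued against by its interferon list median, 112% of the mean of the other UBP1 libraries, and by its UBP1 level (114 CPM, against at most 73.7 CPM in control). UBP1 libraries 2 and 3 held 98.0 and 106 CPM of UBP1, less than the 114 CPM of UBP1 overexpression replicate 1. The libraries further from control in these genes thus did not have the higher measured UBP1 level, which need not measure the amount introduced. What sets the other UBP1 libraries apart stays open, a difference in the response to UBP1 included.

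Abundant genes, chosen after their values were seen, give examples of that difference, all of them large falls. In the fit without UBP1 overexpression replicate 1, the median log2 fold was 0.51 over the 820 genes called higher and -0.99 over the 1309 called lower. TMSB4X had 1555, 1505 and 1036 CPM in control libraries 1, 2 and 3 and 1074, 274 and 271 CPM in UBP1 libraries 1, 2 and 3, and EEF1A1 had 1075, 1339 and 1059 CPM and 1108, 474 and 549 CPM. COX6C had 2469, 2955 and 2576 CPM and 2906, 1173 and 1261 CPM. None of the 3 passed with all libraries (edgeR adjusted p from 0.425 to 0.547), and each passed without UBP1 overexpression replicate 1 (log2 fold of -2.32, -1.18 and -1.13).

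There are 10 splits of the 6 libraries into groups of 3, too few for a share under 0.05. The real split called 17 genes and 4 lists, and the highest of the other splits 0 genes and 2 lists; 1 split, the real one, reached each count. At an unadjusted p under 0.05 the real split had 2260 genes, and the split of control 1, control 2 and UBP1 overexpression 1 against the rest had 2244, which points to a structure of the samples beside the groups.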
